A study of Homo sapiens with 36 samples.

How the data were processed

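RNA from cultures of human intestinal epithelial models was sequenced after poly(A) selection, as 36 libraries with 3 in each of 12 groups. The groups combine the model (IEC or Caco-2), the cytokine challenge (absent or present) and the bacteria (none, stationary or heat-killed). They were assigned from the labels alone, before the data were examined, and replicates have no order. The labels do not say whether replicates came from separate cultures, so the p-values measure only the spread between these libraries. The kit named in the labels can be used with or without strand information and the labels do not state which, so antisense genes are uncertain. The title of the series also mentions human data obtained in vivo, which were not analysed here. Each model came from 1 cell line, and the models differ in origin, medium and days of culture, so the difference between them cannot be assigned to any one of these.

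Per the submitters' processing notes, reads were handled with cutadapt 1.16, HISAT2 2.2.1, SAMtools 1.9, HTSeq 0.11.2 and edgeR 3.36.0 on GRCh38.p13; the settings of these tools are not given in the sources used here. The deposited values are a normalized signal for 62649 Ensembl gene identifiers. The planning before the data were examined assumed library-size scaled values (CPM). The deposited values turned out to be read counts divided by 1 factor per library: after multiplying by that factor, 100% of the values were whole numbers within a tolerance of 0.01. The factors equal the median of ratios to the geometric mean over the 19017 genes above 0 in all 36 libraries. One read amounts to between 0.3139 and 1.6547 on the deposited scale. The reads recovered this way numbered 25.54 to 102.94 Mreads per library (Mreads, reads in units of 10 to the power 6), with a median of 36.67 Mreads. A total of 15352 genes had no reads, and no column was left out.

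Gene symbols (for 42300 identifiers in the table) were assigned from a reference list of gene names. Coordinates come from GENCODE v29 on GRCh38, a release that may differ from that of the submitters. The main test was limma 3.58.1 in R 4.3.3, with an intensity-dependent prior spread, on log2(value + 1), with 1 mean per group. Comparisons within a model used its 18 libraries, and comparisons across models used all 36. Genes needed a value of at least 1 in at least 3 of the fitted libraries. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The comparisons were the challenge, stationary and heat-killed bacteria against none in both states, stationary against heat-killed bacteria, the interaction of stationary bacteria with the challenge, the unchallenged and unexposed models against each other, and the interactions of the model with the challenge and with the bacteria. The interactions were tested because a call in 1 model and none in the other does not show a difference.

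A set of 37 gene lists with 753 genes was fixed before testing and compared with all other genes by camera, with a preset correlation of 0.01 between genes and again with the correlation estimated from the data, for lists with at least 5 tested members. Within each list, calls were also counted after adjustment over the list alone. In comparisons of 2 groups, where all libraries of a group were at 0, the fold is given as a lower bound against 3 reads over that group. Interactions carry no such bound. Their values for genes at 0 in a group, such as KERA, DEFB4A and IDO1 for challenge and model, are as fitted and depend on the pseudocount.

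The genes named in the text follow a rule fixed before the data were examined. In the main comparisons (the challenge, stationary bacteria against none, and the models against each other) these are the 8 largest rises and falls among called genes whose libraries do not overlap and whose higher group mean is at least 5, and in other comparisons the 3 largest. Up to 4 members with the smallest adjusted p are added for each list that was called or had enough called members. Fixed genes of interest are reported whatever their result, except that the results of some genes are not reported here. Clones, pseudogenes and genes without a symbol are not named.

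The alternatives planned before the data were examined were a pseudocount of 0.25, no filter, each library scaled to the same total, the median of ratios within the fitted libraries, the replicate number as a block, only the groups of the contrast in the fit, each library left out in turn, and edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads. Another 6 were added after seeing the data: each library scaled to the mean total, quantile normalization, removal of length and GC trends (10 bins each, for 93.1% of tested genes), reads thinned to 25 Mreads, leaving out both unexposed Caco-2 libraries numbered 1, and the block with only the groups of the contrast. The same total was 1 Mreads, against sums of 31.9 to 44.16 Mreads as deposited, so the pseudocount and the filter weigh more in it (18292 genes tested over both models, against 37997). The mean total changes the total without this. On the recovered reads edgeR and DESeq2 were run as alternatives, since the main test had been fixed for normalized values.

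Whether replicate numbers pair the libraries was checked from the deviations of same-numbered libraries from their group means. All 3 correlations exceeded 0.1 in 0 of 15 pairs of groups in IEC and in 1 of 15 in Caco-2, the unexposed groups without and with the challenge (0.517, 0.348 and 0.407). The blocked count is given beside a result only where the comparison contains these 2 groups and the count moved by over 1.5 times. By a looser measure, 13 of 18 libraries in Caco-2 and 11 of 18 in IEC agreed best with libraries of their own number. The mean correlations in Caco-2 were 0.115 for the same number and -0.057 for different numbers, so weaker pairing of other Caco-2 groups is not excluded. In IEC they were 0.012 and -0.006.

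The scripts were tested on simulated reads with the depths of the real libraries, with genes of a mean of at least 50 changed by known folds. Every group of a model started from the means of its unchallenged, unexposed libraries, with 1 spread per gene for all groups. The real Caco-2 libraries with stationary bacteria were more uneven. In the unchallenged state 32.96% of tested genes were called there, so the rates below need not hold for that comparison. For stationary bacteria in unchallenged IEC limma recovered 82.1%, 95.5% and 100% of genes changed 1.5-fold, 2-fold and 4-fold, with 14 false calls among 35438 genes. For unchallenged Caco-2 it recovered 50.7%, 91.0% and 98.5%, with 14 false calls among 30212 genes, and for the interaction with the model 52.2%, 94.0% and 100%, with 27 false calls among 37997 genes. Camera found the 1 list that was raised 1.3-fold in each simulation, with 0 false lists. The genes were simulated independently of each other. These simulations therefore cannot show how often the preset correlation gives false lists among correlated genes. Other splits of the libraries into 2 sets of 3 were tested exhaustively (10 per comparison), and the interactions with 100 random relabelings, which exchange libraries of the same treatment between the 2 arms after centring each arm. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.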

Results

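RNA sequencing was carried out on 36 libraries from 2 human culture models of the intestinal epithelium. The first model, called IEC here, is an epithelium differentiated from an induced pluripotent stem cell line and kept on culture inserts for 12 days. The second is Caco-2, a colorectal adenocarcinoma line that forms an enterocyte-like layer, grown for 21 days. Each model was studied without and with an inflammatory challenge, which consisted of 2 ng/mL interferon gamma for 24 h and then 1 ng/mL IL-1β plus 10 ng/mL TNFα for 48 h. Either state was combined with no bacteria, with stationary-phase *Lactiplantibacillus plantarum* WCFS1, or with heat-killed cells of that strain. Bacteria were present for 96 h, starting 24 h ahead of the challenge, and medium and bacteria were renewed after 48 h. The labels do not say whether cells without bacteria had their medium changed at that time, so an effect of this change is not separated from that of the bacteria. The 12 resulting groups held 3 libraries each. The depth of the libraries is given under the processing. Levels are given as normalized reads with the SD of 3 libraries. Changes are differences of log2(normalized reads + 1) with their standard error, tested with limma and Benjamini-Hochberg adjustment.

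The first comparison asked what the cytokine challenge does to IEC without bacteria. The rises included genes of the interferon and NF-kB programmes. CXCL9, a T cell attracting chemokine induced by interferon gamma (ENSG00000138755, chromosome 4, 76001275 to 76007488, GRCh38), went from 1.987 ± 1.87 to 1649 ± 42.7 normalized reads, a log2 change of 9.38 ± 0.44 (adjusted p = 1.76e-17). IDO1, the interferon-induced enzyme that degrades tryptophan (ENSG00000131203, chromosome 8, 39902275 to 39928444), rose from 11.47 ± 4.08 to 1655 ± 117 (7.10 ± 0.19, adjusted p = 5.19e-24), and CSF3, the granulocyte growth factor, rose by 7.14 ± 0.28. REG3A, a secreted lectin that kills Gram-positive bacteria (ENSG00000172016, chromosome 2, 79157003 to 79159753), rose from 63.86 ± 5.71 to 5220 ± 253 (6.33 ± 0.15, adjusted p = 1.99e-25). ICAM1, an adhesion receptor for leukocytes, had the smallest adjusted p of all genes (3.89 ± 0.03, adjusted p = 7.37e-36). The anion exchanger SLC26A4 rose by 6.04 ± 0.14, and PIGR, which carries immunoglobulin A across the epithelium, rose from 1441 ± 48.6 to 22660 ± 944. For each of these genes all 3 challenged libraries lay above all 3 unchallenged ones, which the rule for naming the largest rises requires.

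Among the gene lists fixed beforehand, all 17 tested genes of MHC class I presentation rose in challenged IEC (TAP1 2.61 ± 0.05, B2M 1.75 ± 0.03), as did all 25 NF-kB targets (BIRC3 3.78, TNFAIP3 2.72, SOD2 2.96). Of 38 interferon response genes 36 rose and 1 fell (GBP5 3.87, IRF1 1.39 ± 0.04). Of 17 chemokines 15 rose and 1 fell (CXCL8 4.22 ± 0.06, CCL20 4.15, CXCL10 3.83). Of 27 genes of antimicrobial defence 23 rose and 2 fell (NOS2 3.62 ± 0.09, PI3 4.09). The pattern recognition receptors (11 higher, 1 lower of 18; TLR3 1.26, NOD2 1.65), the heat shock genes (12 higher, 1 lower of 16) and the p53 targets (20 higher, 5 lower of 26) moved the same way. Camera called these 8 lists higher, also with an estimated correlation (adjusted p from 2.99e-06 for the NF-kB targets to 0.0203 for the interferon list). MHC class II genes split into 5 higher and 3 lower of 13 and were not called (camera adjusted p = 0.087). HLA-DRA rose by 0.85 ± 0.24 (adjusted p = 0.00527), a call that ended without IEC unchallenged unexposed replicate 3 (0.54, adjusted p = 0.0854). HLA genes, SAA1 and DEFB4A share reads with near-identical copies, so their single values are uncertain.

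Genes of the absorptive enterocyte fell in challenged IEC. CYP3A4, the main intestinal drug-oxidising cytochrome (ENSG00000160868, chromosome 7, 99756960 to 99784265), dropped from 1294 ± 88 to 120.7 ± 12.8 normalized reads (-3.41 ± 0.10). MS4A10, a membrane protein of the small intestine, changed by -3.48 ± 0.11. APOA4, the apolipoprotein of chylomicrons and the most abundant transcript in all 3 unchallenged IEC libraries, went from 549800 ± 28200 to 139900 ± 12800 (-1.98 ± 0.05). Lipid handling (2 higher, 20 lower of 25; APOC3 -2.02, MTTP -1.52), nutrient transporters (2 higher, 20 lower of 24; the fructose carrier SLC2A5 -2.08, the peptide carrier SLC15A1 -1.15), xenobiotic metabolism (6 higher, 18 lower of 32; CYP2J2 -2.06) and brush border enzymes (1 higher, 17 lower of 24; ANPEP -1.73, the lactase LCT -1.59) were called lower, also with an estimated correlation (adjusted p = 0.00351, 0.0118, 0.00351 and 0.0235). SLC9A3, the apical sodium-proton exchanger, was one of the 2 transporters that rose (1.51). Cell cycle genes fell as well (2 higher, 27 lower of 33; CDK1 -1.13, TOP2A -1.04; adjusted p = 0.0135 with an estimated correlation). So did plasma proteins of the fetal liver list (0 higher, 15 lower of 16; FGA -1.38, AFP -0.98; adjusted p = 0.0135 with an estimated correlation). SLC10A1, the bile acid transporter of hepatocytes and not on that list, changed by -3.56 ± 0.09. Mucin and goblet cell genes (5 higher, 15 lower of 22; MUC1 2.02, TFF3 -1.18, ZG16 -1.61) and ribosomal proteins (0 higher, 22 lower of 25) lost their call, with adjusted p = 0.0505 and adjusted p = 0.0949 with an estimated correlation. Tight junction genes split into 5 higher and 8 lower of 21 and were not called. The Paneth cell list (4 higher, 2 lower of 9) had a median of -0.11 but a mean of 1.0 and was called higher (adjusted p = 0.0254 with an estimated correlation), a call that ended with the same total (adjusted p = 0.0764) but not with the mean total (adjusted p = 0.0064).

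In all, 5289 genes were higher and 5593 lower with the challenge in IEC, of 35438 tested, and 885 and 1421 of them changed at least 2-fold. With every library scaled to the same total, 60.5% of the calls were higher, against 48.6% on the deposited scale. That setting also tests fewer genes and gives the pseudocount more weight, so the shares cover unlike sets of genes. Adjusted over the list alone, 37 interferon genes, 24 antimicrobial genes and 12 pattern recognition receptors were higher, and 18 brush border and 28 cell cycle genes were lower; the other counts above changed by at most 2 genes. Markers of other cell types moved too: 11 of 18 mesenchymal genes fell and 1 rose (SPARC -0.55, PDGFRA -1.34; adjusted p = 0.111 with an estimated correlation), 8 of 16 neural genes fell and 1 rose, and of 15 gastric genes 7 fell and 1 rose (MUC5AC -1.83). KERA and ACTL8, at 0 in all challenged libraries, were at least 17.5-fold and 10.8-fold lower.

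**Figure D1:**
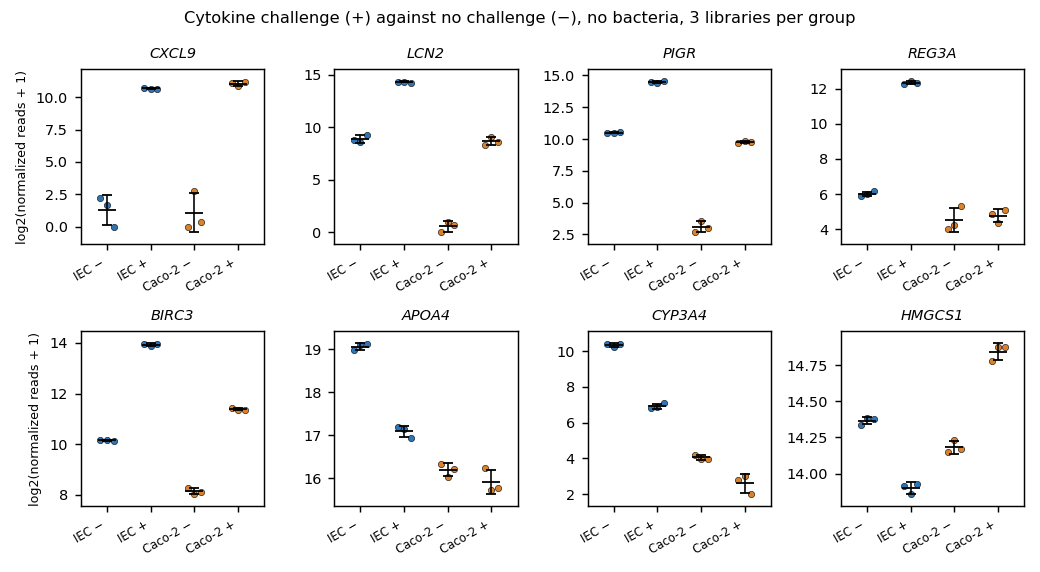
log2(normalized reads + 1) of 8 genes without (−) and with (+) the cytokine challenge in IEC and Caco-2 without bacteria; points are libraries, bars the mean ± SD of 3, and each panel has its own axis range that need not start at 0. CXCL9, LCN2, PIGR and BIRC3 were higher with the challenge in both models, REG3A rose by 6.33 in IEC, and HMGCS1, chosen for display after its values were seen, changed by -0.46 in IEC and by 0.66 in Caco-2.

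The same challenge was then examined in Caco-2 without bacteria. CXCL9 rose from 2.071 ± 3.32 to 2136 ± 259 normalized reads (9.99 ± 0.47, adjusted p = 1.39e-12). LCN2, the iron-scavenging lipocalin released in gut inflammation (ENSG00000148346, chromosome 9, 128149071 to 128153455), rose from 0.5369 ± 0.498 to 418.4 ± 115 (8.11 ± 0.34). PIGR (ENSG00000162896, chromosome 1, 206928518 to 206946466) rose from 7.771 ± 2.71 to 871.9 ± 54.8 (6.68 ± 0.20). EHF, an epithelial transcription factor of the ETS family, rose from 58.45 ± 0.518 to 1386 ± 162 (4.54 ± 0.25). CXCL5, a neutrophil chemokine at 0 in all unchallenged libraries, was at least 174-fold higher. IDO1 was at least 7.19-fold higher; its call (adjusted p = 0.0125) was lost without Caco-2 challenged unexposed replicate 1 (adjusted p = 0.11) or replicate 2 (adjusted p = 0.0681), and DESeq2 gave it no adjusted p.

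In challenged Caco-2, 16 of 17 MHC class I genes (PSMB9 2.92), 5 of 10 MHC class II genes (HLA-DRA 2.44), 24 of 37 interferon genes (IRF1 1.26), 14 of 17 chemokines (CXCL8 4.91 ± 0.52, CCL20 3.79, CXCL10 3.07) and 18 of 24 NF-kB targets (BIRC3 3.24, RELB 2.07, TNFAIP3 2.01, ICAM1 0.87) rose and none of them fell; adjusted over the list alone these counts were 17, 8, 30, 15 and 21. Of 24 antimicrobial genes 17 rose and 1 fell (NOS2 1.01, C3 2.81). Genes of cholesterol synthesis rose (19 higher, 0 lower of 23, 22 higher adjusted over the list alone; ACAT2 0.82, LSS 0.78, FDPS 0.75). So did cell cycle genes (20 higher, 0 lower of 33, 28 higher adjusted over the list alone; CDC6 0.82, RRM2 0.78, E2F1 0.69). Both calls held with an estimated correlation, at adjusted p = 0.0432 and adjusted p = 0.0455; for the 6 immune lists these p-values lay between 0.000291 and 0.0132. Plasma protein genes of the fetal liver list fell (0 higher, 12 lower of 16; FGA -1.53, FGB -1.30, APOH -1.03; adjusted p = 0.0022 with an estimated correlation). The brush border list was called lower with the preset correlation (1 higher, 6 lower of 24, and 3 and 11 adjusted over the list alone; MGAM -0.69, DPP4 -0.63), but with adjusted p = 0.469 with an estimated correlation. KRT4, an epithelial keratin, fell by 2.42. Altogether 1068 genes were higher and 661 lower, of 30212 tested, 341 and 104 of them at least 2-fold. Same-numbered Caco-2 libraries of these groups deviated together. With the replicate number as a block in a fit of only these 6 libraries, a setting added after seeing the data, 4870 genes were called. That fit also leaves out the other groups of the model, and the block in the fit of 18 libraries moved the count far less. In the main model the count was 1073 without Caco-2 unchallenged unexposed replicate 3 and 760 without both libraries numbered 1.

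Whether the challenge response differed between the models was tested as an interaction, with 1941 genes more positive and 2541 more negative in IEC than in Caco-2, of 37997 tested. TNIP3, an inhibitor of NF-kB signalling, had the largest positive difference (6.16 ± 0.30), followed by the defensin gene DEFB4A (6.10 ± 0.58), whose call ended with edgeR (adjusted p = 1.0), and REG3A (6.09 ± 0.54). PIGR (-2.71 ± 0.19) rose more in Caco-2. Of the genes fixed for this comparison, ICAM1 (3.03 ± 0.12) and NOS2 (2.61 ± 0.18) differed, while IRF1 (0.13 ± 0.17), CCL20 (0.36 ± 0.27), CXCL10 (0.76 ± 0.36) and TNFAIP3 (0.71 ± 0.25) did not pass. With each library scaled to the mean total TNFAIP3 passed (0.78, adjusted p = 0.0136), but CCL20 (0.43, adjusted p = 0.306) and CXCL10 (0.81, adjusted p = 0.141) did not. All 3 passed with the same total, which also gives the pseudocount and the filter more weight. IDO1 (4.84) was called by limma but neither by edgeR (1.82, adjusted p = 0.924) nor by DESeq2 (1.86, adjusted p = 0.309), and HLA-DRA (-1.59, adjusted p = 0.0281) lost its call with the same total (-0.25, adjusted p = 0.263) but not with the mean total (-1.56, adjusted p = 0.0272). CXCL8 did not pass either (-0.69 ± 0.60, adjusted p = 0.582), with -0.64 under the mean total and 1.27 with the same total. Cholesterol synthesis (0 higher, 21 lower of 23; INSIG1 -1.90, DHCR7 -1.37), cell cycle (0 higher, 29 lower of 33; CDK1 -1.84, TOP2A -1.51), lipid handling (0 higher, 18 lower of 25; FABP6, an ileal bile acid binding protein, -2.90) and xenobiotic metabolism (1 higher, 18 lower of 32) were more negative in IEC, also with an estimated correlation (adjusted p = 0.0168, 0.00288, 0.00221 and 0.000759). The interferon list was called more positive in IEC (12 higher, 3 lower of 38), but with adjusted p = 0.525 with an estimated correlation. With every library scaled to the same total 56.4% of the interaction calls were positive, against 43.3% on the deposited scale, though over fewer genes tested. Across 28419 genes the changes in the models correlated with r = 0.273 (rho = 0.163), genes not being independent replicates. Over the 15038 genes with a mean of at least 50 over all libraries, r was 0.471. Of the 28419 genes, 550 were higher in both, against 188.2 for independent lists, 418 lower in both, against 120, and 56 and 232 opposite, against 116.5 and 193.8. Independence here takes every gene as equally likely to be called. Calls were more frequent among abundant genes in both models, which by itself raises such overlaps.

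Next, the effect of the bacteria on IEC was tested, without and with the challenge. At an adjusted p under 0.05 limma called 1 gene with stationary bacteria in unchallenged IEC, LRRN4, a leucine-rich repeat protein (ENSG00000125872, chromosome 20, 6040778 to 6054049), at 272.4 ± 23.4 against 372.8 ± 8.13 normalized reads (-0.45 ± 0.07, adjusted p = 0.0393). In challenged IEC it called 4 genes, all lower with stationary bacteria: GUCA2A (ENSG00000197273, chromosome 1, 42162691 to 42164718; -0.35 ± 0.05, adjusted p = 0.0119) and GUCA2B (-0.34, adjusted p = 0.0393), which encode the guanylin peptides that regulate intestinal fluid secretion, the neuropeptide gene NTS (-0.30, adjusted p = 0.0278) and UGT2B11, a glucuronosyltransferase (-0.27, adjusted p = 0.0393). No gene passed with heat-killed bacteria in either state. At an unadjusted p under 0.05 the 4 comparisons gave 2582, 2058, 2910 and 1933 genes (stationary unchallenged, stationary challenged, heat-killed unchallenged, heat-killed challenged), where chance alone gives 1772. Tests on the recovered reads called 9, 50, 34 and 7 genes with edgeR and 0, 60, 30 and 1 with DESeq2, in that order.

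Of the genes fixed for the bacteria, the junction genes TJP1, OCLN and CLDN2, the chemokine CXCL8 and the receptor TLR2 did not pass in any IEC comparison. The fetal liver list was called lower with stationary bacteria in challenged IEC (median -0.17; 0 of 16 over all genes and 15 lower adjusted over the list alone; adjusted p = 0.0364 with an estimated correlation), as was lipid handling (median -0.10, 9 of 25 lower adjusted over the list alone; adjusted p = 0.0301 with an estimated correlation). Between stationary and heat-killed bacteria 1 gene differed in unchallenged IEC, the monocyte chemokine CCL2 (-0.35 ± 0.05, adjusted p = 0.0144), and none in challenged IEC (2365 and 1600 genes at an unadjusted p under 0.05, 8 and 0 with edgeR, 2 and 3 with DESeq2). The interaction of stationary bacteria with the challenge called no gene (1793 at an unadjusted p under 0.05, 3 with edgeR, 0 with DESeq2). These few calls depended on which libraries, scaling or tool were used. LRRN4 was lost without any one of the unchallenged unexposed libraries, or without stationary replicate 1 or 3 (adjusted p up to 0.331). The challenged stationary count became 0 without challenged unexposed replicate 1 or stationary replicate 2, 1 without stationary replicate 1, and 7, 14 and 11 without challenged unexposed replicate 2, unexposed replicate 3 and stationary replicate 3. GUCA2A itself was lost without challenged unexposed replicate 1 (adjusted p = 0.0917) or stationary replicate 2 (adjusted p = 0.19), and GUCA2B, NTS and UGT2B11 were lost with the same total (adjusted p = 0.134 for each). CCL2 was lost with edgeR (adjusted p = 0.0675) and DESeq2 (adjusted p = 0.323), and without stationary replicate 3 (adjusted p = 0.157) or any one heat-killed library (adjusted p = 0.0529, 0.0805 and 0.083).

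**Figure D2:**
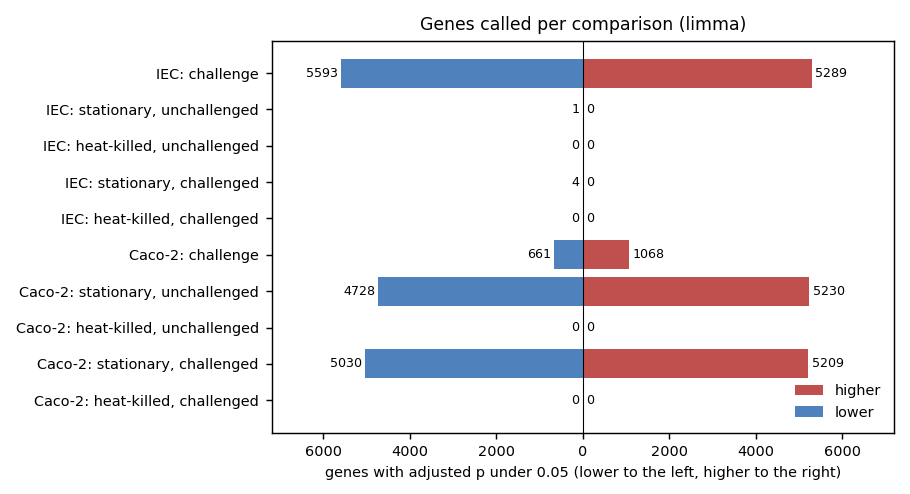
Number of genes called by limma at an adjusted p under 0.05 in 10 comparisons, with lower genes as bars to the left and higher genes to the right. Stationary bacteria gave 5230 higher and 4728 lower calls in unchallenged Caco-2 and 0 and 1 in unchallenged IEC; with every library scaled to the same total the Caco-2 calls were 24.7% higher, against 52.5% on the deposited scale.

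In Caco-2, stationary bacteria went with large changes. In unchallenged cells ANKRD37, a target of the hypoxia-inducible factor (ENSG00000186352, chromosome 4, 185396021 to 185400628), rose from 151.4 ± 15.2 to 2917 ± 1790 normalized reads (4.03 ± 0.36), and in challenged cells by 3.96. The histone genes H2BC21 (3.61 and 4.35) and H1-3 (3.09 and 3.47) rose in both states. INSIG1, a feedback regulator of sterol synthesis (ENSG00000186480, chromosome 7, 155297776 to 155310235), rose by 2.55 ± 0.17 (adjusted p = 4.44e-09) and 2.02, and the tight junction gene CLDN4 (ENSG00000189143, chromosome 7, 73799542 to 73832693) by 1.70 and 1.59. MYC (ENSG00000136997, chromosome 8, 127735434 to 127741434) changed by -1.76 and -1.93, the stem cell receptor LGR5 by -1.43 and -1.82, the cystine carrier SLC7A11 by -1.86 and -1.65, and MT-CYB, a mitochondrially encoded subunit of complex III, by -1.57 and -1.66. Among the largest falls were AMER3 (-3.76) and CYP7A1, the rate-limiting enzyme of bile acid synthesis (-3.21), in unchallenged cells, and MKX (-3.92) and the long noncoding RNA PCAT14 (-3.88) in challenged cells. The libraries with stationary bacteria were uneven, with HSPA1A between 2973.7 and 21058 normalized reads over the 3 unchallenged libraries and between 5577.2 and 24761 over the 3 challenged ones. Each gene has 1 spread over all fitted libraries, including the more even groups. Standard errors and p-values of comparisons with these stationary libraries can therefore be too small. HSPA1A and HSPA1B share reads and are uncertain one by one.

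Within the fixed lists, cholesterol synthesis rose with stationary bacteria in Caco-2 (21 higher, 0 lower of 23 unchallenged and 18 higher, 1 lower challenged; HMGCS1 1.89 and 1.42). The other lists are given in the same order. Immediate early genes rose (15 higher, 0 lower and 14 higher, 0 lower of 23; FOS 2.74 and 2.21, DUSP1 2.45 and 2.51), as did heat shock genes (13 higher, 1 lower and 11 higher, 0 lower of 16; HSPH1 1.59 and 1.49). Glycolysis and hypoxia genes (17 higher, 0 lower and 20 higher, 0 lower of 28; HK2 1.57 and 1.88) and tight junction genes (13 higher, 1 lower and 15 higher, 0 lower of 21; OCLN 0.72 and 0.90, CGNL1 0.95 and 1.02) rose too. So did NF-kB targets (14 higher, 1 lower and 14 higher, 3 lower of 24; BIRC3 2.21 and 1.29). Wnt and stem cell genes fell (0 higher, 11 lower and 0 higher, 10 lower of 18; ASCL2 -1.34 and -1.18, SP5 -1.14 and -1.61). So did the mitochondrially encoded genes (0 higher, 10 lower and 0 higher, 11 lower of 13). Adjusted over the list alone these counts changed by at most 3 genes. All of these camera calls were lost with an estimated correlation (adjusted p from 0.464 to 0.478 in unchallenged and from 0.429 to 0.492 in challenged cells). In challenged cells 16 of 33 cell cycle genes fell and 3 rose (MCM3 -1.06, MCM4 -1.03; adjusted p = 0.597 with an estimated correlation); in unchallenged cells 13 rose and 10 fell, and the list was not called. TJP1 did not pass (0.21, adjusted p = 0.0615, and -0.01, adjusted p = 0.925), but was lower in challenged cells with every library scaled to the same total (-0.32, adjusted p = 0.0106) and passed in unchallenged cells with length and GC trends removed (0.27, adjusted p = 0.0102). CLDN2, which forms a paracellular pore, fell by 0.58 in unchallenged cells (adjusted p = 0.00335), and its change of -0.31 in challenged cells passed only in some alternatives (with the same total -0.59, adjusted p = 0.00426). TLR2 rose in challenged cells (0.54, adjusted p = 0.000409), a call that ended with the same total (0.23, adjusted p = 0.0887), and did not pass in unchallenged cells (0.08). CXCL8 did not pass in either state (0.71 and 0.49), except without Caco-2 challenged stationary replicate 3 (1.35, adjusted p = 0.0166).

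The scaling between libraries matters for this comparison. The normalized reads of the stationary libraries summed to 40.04 ± 2.75 Mreads in unchallenged and 40.42 ± 3.52 Mreads in challenged Caco-2, against 32.62 ± 0.60 and 32.67 ± 0.52 Mreads without bacteria (Mreads, normalized reads in units of 10 to the power 6). On the deposited scale 5230 genes were higher and 4728 lower in unchallenged cells, of 30212 tested, and 5209 higher and 5030 lower in challenged cells, which is 52.5% and 50.9% higher. With every library scaled to the same total these shares were 24.7% and 24.1%, with each library scaled to the mean total they were 22.7% and 21.5%, and the median change of all genes moved to -0.26 and -0.29 under the mean total. Relative to the all-gene median the lists called in the previous paragraph kept their direction under each scaling, but in lists that rose some members moved to the lower side: with the mean total 9 tight junction genes were higher and 5 lower in unchallenged cells, and 12 glycolysis genes higher and 7 lower. Ribosomal protein genes, 25 higher of 25 in both states with medians of 0.58 and 0.45, did not: after quantile normalization the medians were 0.11 with 4 higher and, turned in direction, -0.05 with 1 lower. Nuclear genes of oxidative phosphorylation (13 higher, 0 lower of 27 unchallenged) had a median of 0.25. With the mean total it was -0.05, above the all-gene median of -0.26, and camera no longer called the list. The share of ribosomal protein reads was 10.18% ± 0.65 with and 8.31% ± 0.38 without stationary bacteria in unchallenged cells, and that of mitochondrial reads 2.06% ± 0.27 and 2.73% ± 0.22. Changes in the unchallenged and challenged state correlated with r = 0.67 (rho = 0.648) across genes. Over the 14001 genes with a Caco-2 mean of at least 50, r was 0.906. A total of 4000 genes were higher in both, against 901.7 for independent lists, and 3395 lower in both, against 787.2. Opposite were 5 and 7, against 870.7 and 815.2. Independence here takes every gene as equally likely to be called, though calls were more frequent among abundant genes.

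**Figure D3:**
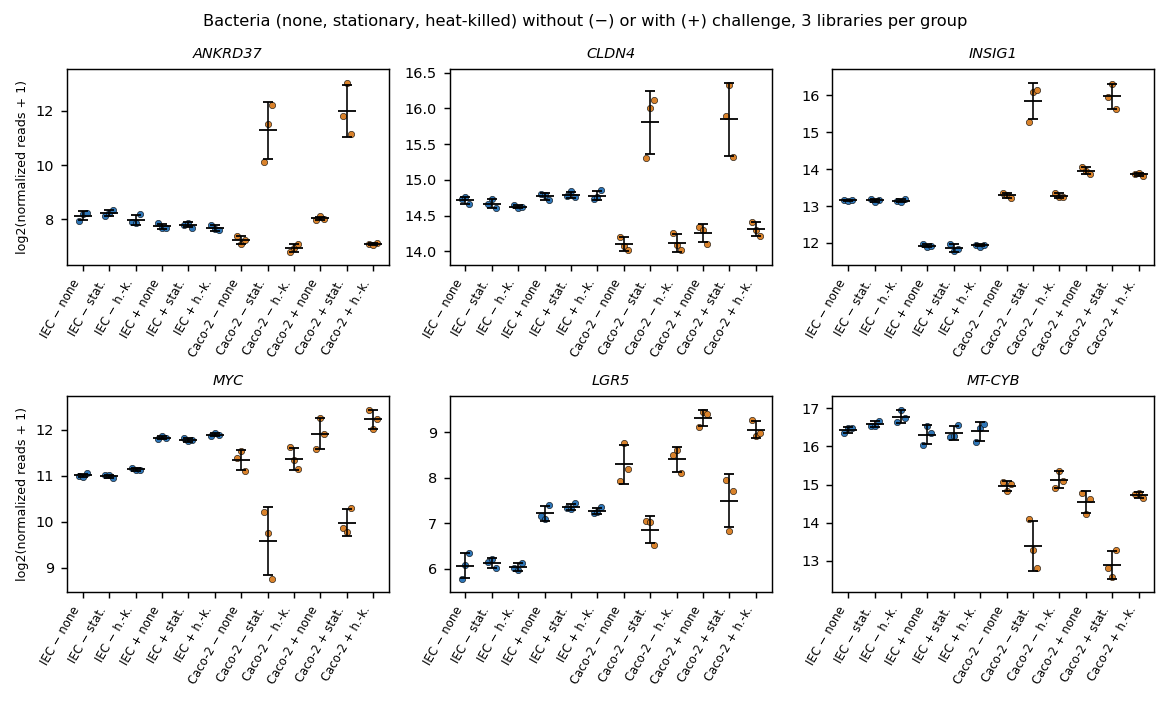
log2(normalized reads + 1) of 6 genes in all 12 groups (none, no bacteria; stat., stationary; h.-k., heat-killed; − and +, without and with challenge); points are libraries, bars the mean ± SD of 3, and each panel has its own axis range that need not start at 0. With stationary bacteria Caco-2 libraries were higher for ANKRD37, CLDN4 and INSIG1 and lower for MYC, LGR5 and MT-CYB, with changes of 4.03, 1.70, 2.55, -1.76, -1.43 and -1.57 in unchallenged cells.

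Heat-killed bacteria gave no call in Caco-2. Limma called 0 genes without and 0 with the challenge (811 and 726 at an unadjusted p under 0.05, where chance gives 1511); this limma fit estimates 1 spread over groups that include the uneven stationary libraries. TJP1, OCLN, CLDN2, CXCL8 and TLR2 did not pass. The metallothionein genes, which bind zinc and copper, had list medians of -2.22 and -1.78, with 0 of 8 passing over all genes and 6 lower adjusted over the list alone (camera adjusted p = 0.35 and adjusted p = 0.565 with an estimated correlation). Without both unexposed libraries numbered 1 the median in unchallenged cells was -1.15.

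Compared directly, stationary and heat-killed bacteria differed in 5418 higher and 5018 lower genes in unchallenged and 5300 higher and 5104 lower in challenged Caco-2, 51.9% and 50.9% of the calls being higher and 25.6% and 24.8% with the same total. ANKRD37 (4.34 and 4.90), H2BC21 (3.67 and 4.34) and the heat shock gene HSPA6 (4.14 and 5.20) had the largest positive differences, and MKX differed by -3.04 and -4.04. OCLN was higher with stationary bacteria (0.67 and 0.82) and CLDN2 lower (-0.74 and -0.46), the challenged call ending with length and GC trends removed (-0.35, adjusted p = 0.0699), without challenged stationary replicate 2 (-0.34, adjusted p = 0.111) or without challenged heat-killed replicate 1 (-0.44, adjusted p = 0.0519). In unchallenged cells TJP1 (0.24, adjusted p = 0.0278) lost its call and turned direction with the same total (-0.05, adjusted p = 0.687), and CXCL8 (1.43, adjusted p = 0.0383) lost it with no filter (adjusted p = 0.0737); TLR2 passed in challenged cells (0.50), but not with the same total (0.19, adjusted p = 0.145). The interaction of stationary bacteria with the challenge in Caco-2 called 11 genes, 5 with a positive and 6 with a negative term. Among these, G0S2, a lipolysis inhibitor (1.19), was 971.4 ± 177 with and 2152 ± 57.4 without stationary bacteria in unchallenged cells, and 1489 ± 209 and 1453 ± 144 in challenged cells. The water channel AQP3 (1.00) was 1007 ± 119 and 869.2 ± 10.9, and then 1693 ± 219 and 729.3 ± 47.7. Both calls ended without unchallenged unexposed replicate 2 (adjusted p = 0.0563) or replicate 3 (adjusted p = 0.0516), and that of AQP3 also without challenged unexposed replicate 2 (adjusted p = 0.0625). With the replicate number as a block 23 genes were called. The count ranged from 0 to 226 with single libraries left out: 226 without unchallenged stationary replicate 1, 34 and 4 without replicates 3 and 2 of that group, 25 without challenged unexposed replicate 3, 4 and 1 without replicates 1 and 2 of that group, 2 without unchallenged unexposed replicate 1, and 0 without replicates 2 or 3 of that group.

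The difference between the models in the effect of stationary bacteria was tested directly. In the unchallenged state 3755 genes were more positive and 4496 more negative in IEC than in Caco-2, and in the challenged state 3740 and 4403. ANKRD37 (-3.95 and -3.91) and H2BC21 (-3.57 and -4.46) were more negative in both states, AMER3 (3.81) more positive in the unchallenged state and PCAT14 (3.95) in the challenged state. Cholesterol synthesis genes were more negative in IEC (0 higher, 21 lower and 1 higher, 19 lower of 23), and so were immediate early genes (0 higher, 14 lower of 23 in both states). Wnt genes were more positive (7 higher, 0 lower and 8 higher, 0 lower of 18), as were mitochondrially encoded genes (10 higher, 0 lower of 13 in both). With an estimated correlation these 4 lists had adjusted p between 0.17 and 0.284. OCLN differed by -0.76 and -0.86, and CLDN2 by 0.71 in the unchallenged state (adjusted p = 0.00137). TJP1 (-0.26, adjusted p = 0.0361, unchallenged) turned to 0.04 with the same total, and TLR2 (-0.64, adjusted p = 0.0076, challenged) lost its call there (-0.30, adjusted p = 0.134). With the same total 76.1% and 76.6% of the calls were positive, against 45.5% and 45.9% on the deposited scale. The same total also tests fewer genes and gives the pseudocount more weight. Across genes the changes in the models correlated with r = -0.044 in the unchallenged and r = -0.002 in the challenged state (rho = -0.081 and -0.023). Over the 15038 genes with a mean of at least 50 over all libraries, r was -0.107 and -0.046. For heat-killed bacteria limma called no interaction (1816 genes at an unadjusted p under 0.05, 1 with edgeR).

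Finally, the unchallenged, unexposed models were compared with each other. DLK1, a fetal Notch-like protein (ENSG00000185559, chromosome 14, 100725705 to 100738224), had the largest difference toward IEC (16.31 on the log2 scale). The neuroendocrine marker CHGA, at 0 in all 3 Caco-2 libraries, was at least 2510-fold higher in IEC. Lists of other lineages were higher in IEC: mesenchyme (17 higher, 1 lower of 18; VIM 5.60, POSTN at least 2580-fold) and gastric genes (14 higher, 1 lower of 15; TFF1 5.13). So were mucins and goblet cells (17 higher, 3 lower of 22; MUC2 9.57) and antimicrobial genes (26 higher, 1 lower of 27; LYZ 2.46, PIGR 7.40). Neural genes (15 higher, 0 lower of 16), endothelial genes (11 higher, 0 lower of 14; KDR at least 445-fold) and tuft and M cell genes (11 higher, 2 lower of 14; DCLK1 at least 304-fold) were higher as well. With an estimated correlation their adjusted p lay between 0.000375 and 0.00638. The mesenchyme median was 5.66, or 5.71 with genes at 0 set to their bound. Fetal liver genes were also higher (13 higher, 2 lower of 16; AFP 2.45, FGA 6.19; adjusted p = 0.0537 with an estimated correlation). Lower in IEC were the meiotic gene SYCP2 (-9.95), HOXA7 (at least 211-fold), the disaccharidase SI (-4.64), LGR5 (-2.22), CDX2 (-0.47) and VIL1 (-1.04), while ALPI was higher (0.96). Cell cycle genes were lower (2 higher, 31 lower of 33; TOP2A -2.94; adjusted p = 0.0312 with an estimated correlation). Brush border genes split into 13 higher and 9 lower of 24 and were not called. Altogether 12649 genes were higher and 9466 lower, of 37997 tested; 57.2% of the calls were higher, 41.2% with the same total and 39.0% with length and GC trends removed. The median difference of all genes was -0.23 with the same total and -0.11 with the mean total, so the direction of small differences between the models depends on the scaling.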

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

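The next 3 paragraphs give results picked out because a test found that an effect differs between 2 sets of groups; the patterns weighed after them include 2 that were noticed in the values. Every test of an explanation below was chosen only after the result was seen.

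The effect of stationary bacteria differed with the challenge in Caco-2 for 11 genes, among them G0S2 (1.19), AQP3 (1.00), RARRES1 (0.93), TNFRSF9 (-1.96), UNC13A (-1.25) and PAQR4 (-0.84). In 9 of 100 relabelings of the libraries, the real one included, at least as many genes were called, and the highest count of another relabeling was 1187, so chance is not excluded. A count of 1187, many times the real one, points to a structure of these libraries whose source was not tested.

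The response to the challenge differed between IEC and Caco-2 for 4482 genes, with TNIP3 (6.16), DEFB4A (6.10) and REG3A (6.09) more positive and KERA (-4.11), CALCR (-3.92) and HBB (-3.77) more negative in IEC. The calls of DEFB4A, KERA and HBB ended with edgeR, and DESeq2 gave KERA and HBB no adjusted p. Of 100 relabelings 1, the real one, gave as many calls, and the highest other count was 860.

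The effect of stationary bacteria differed between the models for 8251 genes without the challenge. AMER3 (3.81), NPY4R (3.54) and SVOP (3.47) were more positive in IEC, and ANKRD37 (-3.95), H2BC21 (-3.57) and DHH (-3.51) more negative. With the challenge it differed for 8143 genes, PCAT14 (3.95), FLRT1 (3.65) and MKX (3.45) being more positive and H2BC21 (-4.46), HSPA6 (-4.31) and ANKRD37 (-3.91) more negative. Of 100 relabelings 1, the real one, gave as many calls in each state, and the highest other counts were 6617 and 5813. A relabeling that exchanges only part of the libraries keeps part of a real difference, so these counts do not measure chance alone.

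The first pattern weighed is the many calls with stationary bacteria in unchallenged Caco-2 beside the few in unchallenged IEC. The challenged state, with 10239 calls in Caco-2 and 4 in IEC, was not put to the tests of this paragraph. Low power in IEC could hide the same response, but over 9871 genes called in Caco-2 the median IEC change in the Caco-2 direction was -3.02% of the Caco-2 median (-5.91% to -0.67% over the 9 pairs of IEC libraries), which argues against it. The values also argue against the scaling, since the smallest Caco-2 count over 6 scalings was 9686 and the largest IEC count 1, and against depth, with 9283 calls in Caco-2 and 0 in IEC after thinning. A biological difference between the models remains a hypothesis, and their origin, medium and days of culture may each explain it.

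The second pattern is that on the deposited scale, calls with stationary bacteria in unchallenged Caco-2 were more often higher among the most abundant of 3 equal sets of genes (3811 higher, 2330 lower) and more often lower among the least abundant (179 higher, 354 lower). A few genes taking most of the reads could cause this, but without the 50 most abundant genes the summed values still had a ratio of 1.2 (1.23 with all genes), which argues against it. A shift of the whole distribution does not account for the calls, 83.8% of which kept their direction after quantile normalization. Which direction prevails depends on the scaling: the most abundant set had 1788 higher and 4842 lower with the mean total. Such a total moves all but the scarcest genes of a library alike, so these counts do not show where the difference between sets comes from. The median log2 changes from the least to the most abundant set were -0.10, -0.10 and 0.10 as deposited. With the mean total they were -0.23, -0.37 and -0.20. The least abundant set, with means up to 5.63, lies near the pseudocount. Quantile normalization (2818 higher and 3067 lower) gives every library the same distribution, which largely removes such a difference, so it cannot decide either. Removing length and GC trends left 126% of the gap between the outer sets, which argues against those trends. Whether the cells hold more or less RNA was not measured, so the cause stays open.

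The last pattern is the lower metallothionein genes with heat-killed bacteria in Caco-2, whose unexposed libraries numbered 1 had the highest levels. Without these libraries the median in unchallenged cells was -1.15, and the lowest unexposed list mean (4.73) lay under the highest heat-killed one (4.81), so there the test cannot tell whether 1 unexposed library could be the cause. In challenged cells every unexposed library left lay above every heat-killed one (lowest 5.87 against highest 5.41). Reads shared between paralogs would leave the summed reads of the list unchanged, but their log2 ratio of -2.11 was -0.78 without unexposed library 1, so this could not be decided either. Metal content of the medium is a possible cause that was not tested.

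For comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. As many calls as the real one were found in 1 split, the real one, with a highest other count of 0, for the challenge in IEC and in Caco-2, for stationary bacteria in Caco-2 in either state against none and against heat-killed bacteria, and for the models against each other. Every other split mixes libraries of both groups in each set, so a large real difference goes into the spread. A highest other count of 0 beside many real calls is then largely by construction, and no conclusion is drawn from it. Where the real count is 0 every split gives as many by construction, so such a number tells nothing. In IEC the numbers were 3 for stationary bacteria (highest other count 8), 10 for heat-killed bacteria (3) and 3 for stationary against heat-killed bacteria (3) without the challenge. With the challenge they were 2 (51), 10 (21) and 10 (0). The split with 51 calls for challenged stationary IEC, several times the real 4, points to a structure of these libraries. For heat-killed bacteria in Caco-2 the numbers were 10 (1) without and 10 (0) with the challenge. For the interaction of stationary bacteria with the challenge in IEC and for heat-killed bacteria and the model the real count is also 0, so all 100 relabelings give as many by construction (highest 22 and 1).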

How the results depend on the processing

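Of 26887 values of named genes under alternatives, 26281 were counted as unchanged, 556 lost and 29 gained the call, and 21 turned direction. A turn was counted only where the gene was called in the main fit or under the alternative. Turns of genes called in neither fit are among the unchanged values. Of 4171 values of gene lists 3593 kept direction and call, 577 lost the call and 1 turned in camera's direction while called. Lists that lost the call may also have turned. Camera was rerun with an estimated correlation, the pseudocount, the same total, the mean total, the block and libraries left out, not with the other scalings, under which only list medians and member counts were computed. For counts below the cause of a change was not tested, and the mean total, quantile normalization, length and GC trends, thinning, leaving out both Caco-2 libraries numbered 1 and the block with only the contrast's groups were chosen after seeing the data. A library left alone or in a pair is assumed to vary like the other groups. Depth limits scarce genes, 1 read being up to 1.6547 in the table's unit.

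The challenge in Caco-2 gave 1729 calls, 760 without both libraries numbered 1, 1073 to 1611 with single libraries left out, 4870 with the replicate block and only the contrast's groups, and 1914 with the block in the fit of 18. The numbers pair these libraries, and this fit of the 6 libraries changed no call of its named genes.

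In the other comparisons at least 1 pair of groups did not meet the rule for pairing by number, though weaker pairing in Caco-2 is not excluded. The interactions of the challenge in Caco-2 and with the model also contain the 2 paired groups. Stationary bacteria in unchallenged IEC (1 call) gave 0 with no filter, the same total, the mean total, thinning, the replicate block and DESeq2, 9 with edgeR, and 0 to 3 with single libraries left out. Heat-killed bacteria in unchallenged IEC (0) gave 2 with no filter and the same total, 1 with the median of ratios, the mean total and quantile normalization, 19 with the replicate block, 11 with length and GC trends removed, 6 with only the contrast's groups, 34 with edgeR, 30 with DESeq2, and 0 to 4. Stationary bacteria in challenged IEC (4) gave 2 with a pseudocount of 0.25 and the median of ratios, 0 with no filter, 1 with the same and the mean total, 13 with the replicate block, 50 with edgeR, 60 with DESeq2, and 0 to 14. Heat-killed bacteria in challenged IEC (0) gave 7 with edgeR and 1 with DESeq2. Stationary against heat-killed bacteria gave in unchallenged IEC (1) 2 with no filter, 3 with the same total, 0 with thinning and with only the contrast's groups, 8 with edgeR, 2 with DESeq2, and 0 to 2, and in challenged IEC (0) 3 with DESeq2 and 0 to 2. The interaction of stationary bacteria and challenge in IEC (0) gave 1 with the replicate block, 3 with edgeR, and 0 to 3, and in Caco-2 (11) 35 with the same total, 23 with the replicate block, 41 with quantile normalization, 4 with length and GC trends removed, thinning and only the contrast's groups, 0 without both libraries numbered 1, 25 with edgeR, 238 with DESeq2, and 0 to 226. Heat-killed bacteria in Caco-2 (0) gave 0 to 3 in unchallenged cells and 3 with only the contrast's groups in challenged cells. Their interaction with the model (0) gave 8 with no filter, 1 with only the contrast's groups and with edgeR, and 0 to 4. Camera called 315 lists over all comparisons, 50 with an estimated correlation.

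These values turned direction, counting only those called in the main fit or under the alternative. With quantile normalization MT-CO1 was 0.07 for the challenge in IEC, AGR2 0.00 and SLC40A1 -0.04 for stationary bacteria in unchallenged Caco-2, RPL10 -0.01, RPL7 -0.01 and FBLN1 -0.02 in challenged Caco-2, EZR -0.01, SLC40A1 -0.13 and COX4I1 -0.05 against heat-killed bacteria in unchallenged and FBLN1 -0.03 in challenged Caco-2, SERPINA1 0.78 for challenge and model, TJP1 0.00 for stationary bacteria and model without and C3 0.05 and RPS23 0.01 with the challenge. With the same total CXCL5 was 2.51, CCL25 0.21 and CXCL8 1.27 for challenge and model, but -2.39, -2.63 and -0.64 with the mean total, so the total alone does not turn them. With the same total and with the mean total TJP1 was -0.05 against heat-killed bacteria in unchallenged Caco-2 and 0.04 for stationary bacteria and model. Without IEC unchallenged unexposed replicate 1 the interferon list was 0.06 for stationary bacteria in unchallenged IEC, and between -0.17 and 0.06 over all libraries left out.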

Other observations

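In unchallenged IEC with heat-killed bacteria limma called 0 genes over all genes (2910 at an unadjusted p under 0.05, 34 with edgeR, 30 with DESeq2, 19 with the replicate block and 11 with length and GC trends removed). All 13 mitochondrially encoded genes were higher when adjusted over the list alone, with a median of 0.31 (MT-ND6 0.46, MT-ATP6 0.37, MT-CYB 0.34), and camera called the list with the preset correlation (adjusted p = 6.03e-16) but not with an estimated correlation (adjusted p = 0.185). These genes are transcribed as long units from 1 genome, so they are not independent. The share of mitochondrial reads was 4.86% ± 0.51 with heat-killed bacteria, 4.4% ± 0.15 with stationary bacteria and 4.07% ± 0.26 without. The heat-killed libraries had 4.39%, 5.41% and 4.78%.

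Stationary against heat-killed bacteria in unchallenged IEC gave lower chemokine genes, with 0 higher and 1 lower of 17 over all genes and 7 lower adjusted over the list alone (median -0.15; CXCL3 -0.22, CXCL6 -0.25, CXCL10 -0.56; adjusted p = 0.00342 with an estimated correlation). CXCL1 (-0.15) shares reads with CXCL2 and is uncertain.

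The challenge was also compared within the groups with heat-killed bacteria. It called 5228 higher and 5596 lower genes in IEC and 1393 higher and 817 lower in Caco-2.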
